A study of Mus musculus with 12 samples.

How the data were processed

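Whole bone marrow RNA of 12 mouse libraries was analysed from 1 table of gene counts. Per the labels' protocols, total RNA was extracted with a mirVana kit, polyadenylated RNA was selected, and strand-specific libraries were made with a NEBNext directional kit that marks the second cDNA strand with dUTP. The same protocol text names globin-depleted RNA as another possible input and does not say which libraries, if any, had it. The values are whole-number counts per gene as the authors deposited them, not normalised, with 1 column per library. TopHat2, a spliced read aligner, and the mouse genome build mm10 are named in the submitters' processing notes, without versions or settings. The counting program, its strand setting and the gene annotation are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain.

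Groups were taken from the labels, which name injury and antibody for each library and number the libraries 1 to 12 with no number shared between groups, so no pairing was modelled. The labels do not state that each library came from a separate mouse, and p-values then measure the spread between these libraries, which may be technical. Total counts ran from 18780399 to 25708084 per library. Chi-square tests of counts over genes gave 6.21 to 35.9 per degree of freedom for the 18 pairs within groups, so no pair looked like 1 library deposited under 2 names. Of 24415 genes 24334 had an Entrez identifier in the RefSeq table of GRCm38.p6, 24329 of these on the same chromosome, and 98.5% overlapped the position given there. Of 14701 genes with the same end in both sources, 11377 started 1 lower and 300 at the same base, so starts were read as counting from 0 and raised by 1. Spreadsheet software had turned 27 symbols into dates, which were restored from the identifiers, and 11 symbols were blank. The table held 0 genes with mitochondrial names, so the planned mitochondrial share was not computed.

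Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries scaled with TMM factors, and a quasi-likelihood model with robust dispersions was fitted to all 12 libraries with 1 mean per group, which leaves 9 residual degrees of freedom. Each of the 3 comparisons was tested 2-sided with Benjamini-Hochberg adjustment at 0.05. Gene means are CPM with SD over 4 libraries, and fold changes are log2 with SE. The SE was derived as the size of the log2 fold change over the square root of the quasi-likelihood F. Shares of counts and scores were compared with 2-sided exact permutation tests over the 70 assignments of 4 and 4 libraries, whose smallest p is 0.0286 by that exact test. The 24 gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Some genes belong to more than 1 list. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for shares, permutation tests and plots.

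The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The rule names Spic, Csf3, Csf3r, Gata1, Klf1, Epor, Vcam1 and Hmox1. It adds the 5 largest rises and 5 largest falls among genes past the threshold with an average log2 CPM of at least 3 and no overlap between groups, leaving out predicted or unnamed models and immunoglobulin and T cell receptor segments. It also takes up to 3 members of each list with the smallest p, of which the text names some, and a gene named in 1 comparison may be given in others. A gene that the rule names between the burn groups is not reported here. Maea, Nfe2, and Xbp1 after burn, members that moved against their list, were named after their values were seen. Lists of genes typical of 9 tissues (brain, heart, lens, liver, kidney, lung, skin, gut and testis) were chosen after seeing the data. The brain score is the mean log2 CPM of the 18 brain genes, and a gene was said to follow it when its slope on the score within groups exceeded 0.5 with an adjusted p under 0.05.

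The alternatives were DESeq2 size factors, upper quartile and library-size scaling, hemoglobin genes or the 20 most abundant genes left out, no filter beyond a count above 0, CPM above 1 in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with and without sample weights, only the groups compared, each library left out in turn, an adjusted p of 0.01 and a test against a 1.5-fold change. The brain score as a covariate, alone and with an estimated correlation in camera, the genes that follow it left out, and replicates 9 and 12 left out were added after seeing the data. On simulated counts for 15283 genes with 50 seeded genes each at 1.5, 2, 3 and 4-fold, the test recovered 28, 41, 43 and 44 for burn against sham, with 13 of 169 calls false. It recovered 26, 38, 39 and 46 for the comparison of burn groups, with 10 of 159 calls false, and 32, 39, 39 and 46 for burn with anti-G-CSF against sham, with 7 of 163 false. Simulated genes varied independently of each other, without a shared signal such as that of the brain genes. The false calls therefore do not show how many such a signal would cause in the real libraries.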

Results

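RNA from whole bone marrow of female C57BL/6J mice, 8 weeks old, was sequenced from 12 libraries, 4 in each of 3 groups. Mice received sham treatment with an isotype control antibody (replicates 1 to 4), a flame burn with the isotype antibody (replicates 5 to 8), or a flame burn with an antibody that neutralises granulocyte colony-stimulating factor (G-CSF, the cytokine that drives neutrophil production, replicates 9 to 12). The antibody was first given 12 hours before injury, again at injury and then daily, and marrow was taken on day 7. The study asked whether G-CSF induced by burn depletes erythroblastic island macrophages, the marrow macrophages around which red cell precursors mature and which express the transcription factor Spi-C, and with them red cell production. Sham mice given the anti-G-CSF antibody were not analysed here. The libraries held 18780399 to 25708084 gene counts each, and 15283 of the 24415 genes in the table passed the expression filter.

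The neutrophil genes S100a8, S100a9, Ngp and Ltf together took 3.74% ± 0.423 (SD, n = 4) of all gene counts in sham marrow, 6.65% ± 0.240 after burn and 2.58% ± 0.223 after burn with anti-G-CSF. Each of the 3 differences had p = 0.0286 in a 2-sided exact permutation test, the smallest p that 4 against 4 libraries allow, and the same value after Benjamini-Hochberg adjustment over the 3 tests. The ribosomal RNA precursor Rn45s took 0.142% ± 0.0166 in sham, 0.142% ± 0.0334 after burn and 0.242% ± 0.0609 after burn with anti-G-CSF. The last group differed from each of the others (exact permutation test, p = 0.0286, adjusted p = 0.0429). Adult alpha and beta hemoglobin genes were listed at 0 in all libraries but replicate 8, which held 2 counts, so the hemoglobin share rested on 4 to 55 counts per library, nearly all of other hemoglobin genes. It was 0.445 times the sham share after burn and 3.06 times the burn share with anti-G-CSF (exact permutation test, p = 0.0286 and adjusted p = 0.0429 for both). Its ratio between burn with anti-G-CSF and sham was 1.36 (exact permutation test, p = 0.629, adjusted p = 0.629).

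Transcripts typical of brain, heart and lens were present in all 12 libraries, at levels that differed between libraries. They included Camk2a and Snap25 of neurons, Myh6 of heart muscle and Cryaa of lens. The summed level of 18 brain genes was 777 ± 86.7 CPM (counts scaled to a common library total, SD, n = 4) in sham, 909 ± 384 in burn and 1795 ± 638 in burn with anti-G-CSF. Summed heart genes stood at 510.3 ± 54.5, 609 ± 275 and 1251 ± 450.4 CPM in the same order, and summed lens genes at 127 ± 15.3, 151 ± 61.1 and 299.7 ± 114 CPM. Among the other tissues tried (liver, kidney, lung, skin, gut and testis), the highest group mean was 14.2 ± 3.82 CPM, for liver in burn with anti-G-CSF. At these low levels liver genes, at 6.44 ± 1.09 in sham and 8.64 ± 3.93 in burn, rose in the same order of groups. Lung genes did so too, at 5.17 ± 0.977, 6.88 ± 2.81 and 12.9 ± 5.41 CPM, while kidney, skin, gut and testis genes did not. The brain level differed between burn with anti-G-CSF and sham with p = 0.0286 in an exact permutation test (adjusted p = 0.0857 over 3 comparisons). Between burn with anti-G-CSF and burn the exact permutation p = 0.0857 (adjusted p = 0.129), and between burn and sham the exact permutation p = 0.571 (adjusted p = 0.571). The level was highest in replicates 9 and 12 and lowest in replicate 6. Rn45s shares ranked as the brain level did within each of the burn groups. Within sham they did not, as replicate 1 had the highest Rn45s share and the lowest brain level. Whether the Rn45s difference between groups came with these transcripts was not tested.

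**Figure D1:**
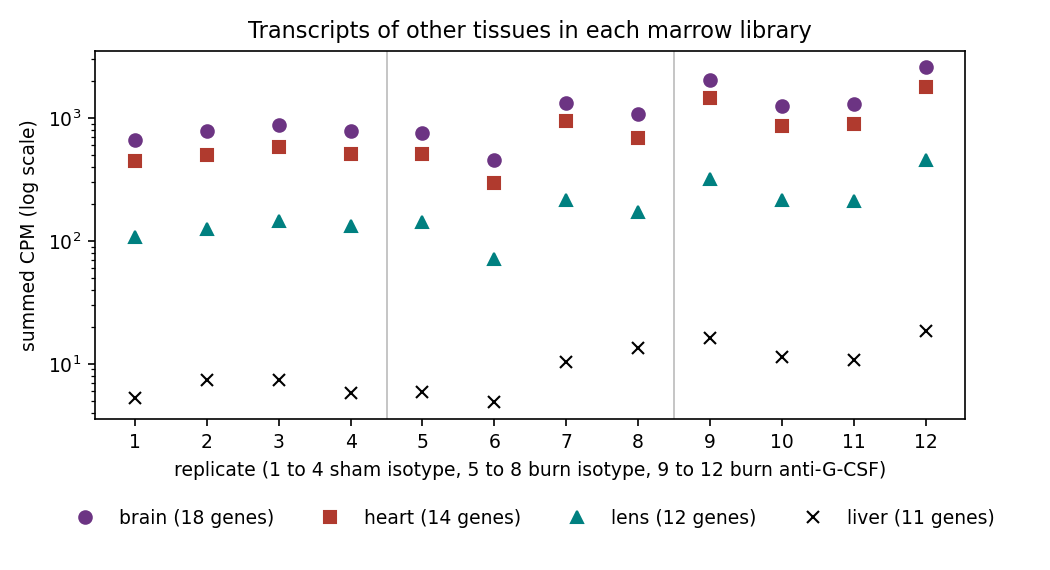
Summed CPM of genes typical of brain, heart, lens and liver (vertical axis, log scale) in each of the 12 marrow libraries (horizontal axis, replicate number). Each point is 1 library, and the brain level ranges from 455 to 2581 CPM, with heart and lens points running parallel to it.

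Burn with isotype was compared with sham with isotype to ask what the injury changed in marrow by day 7. Red cell, resident macrophage and lymphoid genes fell after burn, while neutrophil and monocyte genes rose, though no list passed with an estimated correlation between genes (lowest adjusted p = 0.0627). Spic (Entrez gene 20728, chromosome 10, 88675270 to 88683023 in mm10) fell from 16.5 ± 1.94 CPM (SD, n = 4) to 8.81 ± 2.38 CPM, a log2 fold change of -0.90 ± 0.20 (SE, adjusted p = 0.00351, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for all gene tests). Alas2, the first enzyme of heme synthesis in red cell precursors (Entrez gene 11656, chromosome X, 150547417 to 150570622), fell from 3086 ± 117 to 1361 ± 239.8 CPM, a log2 fold change of -1.18 ± 0.15, adjusted p = 5.30e-05. In total 1691 genes were higher and 1516 lower of 15283 tested, of which 131 and 150 changed over 2-fold.

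All 12 tested genes of heme synthesis and its transport fell (12 adjusted over the list alone), while the 6 adult globin genes placed in the same list were too low to be tested. The heme synthesis list had a median log2 fold change of -0.67 (camera adjusted p = 5.66e-15, and adjusted p = 0.0715 with an estimated correlation). All 17 red cell membrane and cytoskeleton genes fell (17 adjusted over the list alone), among them the water channel Aqp1, at -0.83 ± 0.11, adjusted p = 6.20e-05. The red cell membrane list had a median of -0.73 (camera adjusted p = 2.41e-20, and adjusted p = 0.0715 with an estimated correlation). Of 20 erythroid transcription factors and maturation genes 19 fell (19 adjusted over the list alone). The erythroid factor list had a median of -0.77 (camera adjusted p = 7.24e-20, and adjusted p = 0.0676 with an estimated correlation). Among them were Gata1, the master regulator of erythroid genes (-0.73 ± 0.11, adjusted p = 1.92e-04), Klf1 (-0.83 ± 0.12, adjusted p = 1.57e-04), the erythropoietin receptor Epor (-0.77 ± 0.13, adjusted p = 7.08e-04), the carbonic anhydrase Car1 (-0.82 ± 0.10, adjusted p = 3.77e-05) and the repressor Gfi1b (-1.02 ± 0.13, adjusted p = 3.94e-05). Of 18 iron handling genes 9 fell and 4 rose (4 higher and 10 lower adjusted over the list alone). The iron handling list had a median of -0.28 (camera adjusted p = 0.0171, and adjusted p = 0.241 with an estimated correlation). The riser with the smallest p was Hp, at 1.09 ± 0.13, adjusted p = 2.13e-05, which encodes the hemoglobin scavenger haptoglobin and is also a neutrophil granule gene.

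Of 22 erythroblastic island and resident macrophage genes 15 fell and 1 rose (2 higher and 17 lower adjusted over the list alone). The island macrophage list had a median of -0.76 (camera adjusted p = 1.33e-13, and adjusted p = 0.0627 with an estimated correlation). The adhesion molecule Vcam1 changed by -0.84 ± 0.10, adjusted p = 2.74e-05, the mannose receptor Mrc1 by -0.89 ± 0.11, adjusted p = 2.62e-05 and the heme oxygenase Hmox1 by -0.72 ± 0.15, adjusted p = 0.00308. The riser was Maea, an adhesion protein of erythroblasts and macrophages. Of 16 monocyte genes 11 rose (13 higher and 1 lower adjusted over the list alone), among them Ms4a6c (0.75 ± 0.09, adjusted p = 2.71e-05) and the oxidase subunit Cybb (0.78 ± 0.12, adjusted p = 1.42e-04). The monocyte list had a median of 0.64 (camera adjusted p = 1.34e-08, and adjusted p = 0.155 with an estimated correlation).

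Neutrophil genes of each maturation stage rose. Of 13 primary granule genes 11 rose (12 adjusted over the list alone), including the protease Prtn3 (1.11 ± 0.11, adjusted p = 6.81e-06). The primary granule list had a median of 0.65 (camera adjusted p = 5.01e-15, and adjusted p = 0.0627 with an estimated correlation). All 16 secondary and tertiary granule genes rose (16 adjusted over the list alone), with Wfdc21 at 1.04 ± 0.10, adjusted p = 3.79e-06. The secondary granule list had a median of 0.90 (camera adjusted p = 6.79e-26, and adjusted p = 0.0627 with an estimated correlation). Of 18 mature neutrophil genes 14 rose (15 adjusted over the list alone), including Slfn4 (1.36 ± 0.13, adjusted p = 5.04e-06) and S100a8, which went from 11558 ± 1755 to 22675 ± 1069.7 CPM (0.97 ± 0.11, adjusted p = 1.79e-05). The mature neutrophil list had a median of 0.75 (camera adjusted p = 2.59e-18, and adjusted p = 0.0632 with an estimated correlation). Of 14 G-CSF and STAT3 signalling genes 11 rose (11 adjusted over the list alone). The STAT3 signalling list had a median of 0.69 (camera adjusted p = 4.31e-08, and adjusted p = 0.0914 with an estimated correlation). It shares Csf3r with the mature neutrophil list. Whether its changes, here and with anti-G-CSF, came from the share of neutrophils or from signalling was not tested. Socs3, a feedback inhibitor induced through STAT3 (Entrez gene 12702, chromosome 11, 117966087 to 117969366), rose by 1.51 ± 0.18, adjusted p = 2.74e-05, Stat3 by 0.71 ± 0.10, adjusted p = 6.21e-05 and the G-CSF receptor Csf3r by 0.51 ± 0.11, adjusted p = 0.00349. Csf3, which encodes G-CSF, had 2 counts in replicate 1 and 0 elsewhere and was not tested. Of 10 myeloid suppressor and alternative activation genes 5 rose and 1 fell (6 higher and 1 lower adjusted over the list alone). The suppressor list had a median of 0.52 (camera adjusted p = 0.00222, and adjusted p = 0.0627 with an estimated correlation).

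Lymphoid genes and those of granulocytes outside the neutrophil lineage fell. Of 20 B lineage genes 18 fell (20 adjusted over the list alone), the adaptor Blnk at -1.07 ± 0.11, adjusted p = 1.32e-05. The B lineage list had a median of -1.08 (camera adjusted p = 7.24e-20, and adjusted p = 0.0627 with an estimated correlation). Of 8 plasma cell genes 5 fell and 1 rose (1 higher and 6 lower adjusted over the list alone), with Mzb1 at -1.29 ± 0.16, adjusted p = 4.17e-05 and Xbp1, a transcription factor of secretory cells, at 0.40 ± 0.10, adjusted p = 0.00800. The plasma cell list had a median of -1.08 (camera adjusted p = 7.49e-05, and adjusted p = 0.107 with an estimated correlation). Of 14 dendritic cell and MHC class II genes 9 fell (10 adjusted over the list alone), including the class II activator Ciita (-0.96 ± 0.14, adjusted p = 1.41e-04). The dendritic cell list had a median of -0.81 (camera adjusted p = 4.10e-07, and adjusted p = 0.103 with an estimated correlation). Of 17 T and NK cell genes 10 fell (1 higher and 14 lower adjusted over the list alone), with the T cell kinase Lck at -0.88 ± 0.13, adjusted p = 1.61e-04. The T and NK cell list had a median of -0.72 (camera adjusted p = 1.61e-06, and adjusted p = 0.221 with an estimated correlation). Of 15 eosinophil, basophil and mast cell genes 12 fell (13 adjusted over the list alone), and the basophil protease Mcpt8 stood at -0.69 ± 0.12, adjusted p = 4.41e-04. The eosinophil and basophil list had a median of -0.69 (camera adjusted p = 9.93e-08, and adjusted p = 0.125 with an estimated correlation).

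Of 28 cell cycle genes 13 fell (14 adjusted over the list alone), Cdc6 at -0.39 ± 0.08, adjusted p = 0.00174. The cell cycle list had a median of -0.20 (camera adjusted p = 5.73e-05, and adjusted p = 0.346 with an estimated correlation). Of 14 megakaryocyte and platelet genes 1 fell, Tubb1 at -0.68 ± 0.18, adjusted p = 0.0147 (1 adjusted over the list alone, camera adjusted p = 0.0236, and adjusted p = 0.655 with an estimated correlation). Of 17 stem and progenitor genes 2 rose and 1 fell (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.965), and the list's median, -0.02, and mean, 0.01, had opposite signs. Of 24 interferon response genes 3 fell and 2 rose (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.255), with the antiviral Rsad2 at -0.76 ± 0.15, adjusted p = 0.00183. Of 19 inflammatory cytokine and NF-kB target genes 2 rose and 1 fell (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.912), with Tnf at 0.68 ± 0.16, adjusted p = 0.00426. In lists for other tissue in or near bone, of 15 stroma and osteoblast genes 1 rose and 1 fell (1 adjusted over the list alone, camera adjusted p = 0.452), of 14 endothelial genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.301) and of 11 skeletal muscle genes 1 fell (1 adjusted over the list alone, camera adjusted p = 0.451).

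Among genes with an average log2 CPM of at least 3 and no overlap between the 4 burn and 4 sham libraries, the largest rises were in Prok2, a secreted chemoattractant (2.93 ± 0.47, adjusted p = 8.14e-04), the lipase Lipg (Entrez gene 16891, chromosome 18, 74939322 to 74961263, 2.70 ± 0.36, adjusted p = 2.50e-04), the proteoglycan Vcan (Entrez gene 13003, chromosome 13, 89655310 to 89742512, 2.55 ± 0.11, adjusted p = 2.39e-10), the uridine phosphorylase Upp1 (2.42 ± 0.17, adjusted p = 3.21e-07) and Wfdc17 (2.10 ± 0.18, adjusted p = 5.83e-06). Vcan went from 20.6 ± 2.50 to 121 ± 14.7 CPM. The largest falls were in the chemokine receptor Ccr7 (-1.37 ± 0.18, adjusted p = 4.62e-05), the lectin Cd209a (-1.34 ± 0.19, adjusted p = 8.36e-05), the IgE receptor Fcer2a (-1.31 ± 0.33, adjusted p = 0.0138), the T cell factor Tcf7 (-1.31 ± 0.28, adjusted p = 0.00368) and Rec114 (-1.29 ± 0.16, adjusted p = 2.72e-05). With library-size scaling alone the split was 1276 higher and 2846 lower, with a median log2 fold change over all genes of -0.10. With the brain score as a covariate the iron handling list was at -0.27 (camera adjusted p = 0.0801) and the interferon list, with a median of -0.040 without it, at 0.010 (camera adjusted p = 0.776), and no other list changed its call or the sign of its median. The genes that passed in the eosinophil and basophil list then numbered 9, in the monocyte list 13 and in the cell cycle list 11. With an estimated correlation between genes the lowest adjusted p of the 24 lists was 0.0627, and 6 lists passed when the brain score was also a covariate. Fry called 17 lists, 6 higher and 11 lower.

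**Figure D2:**
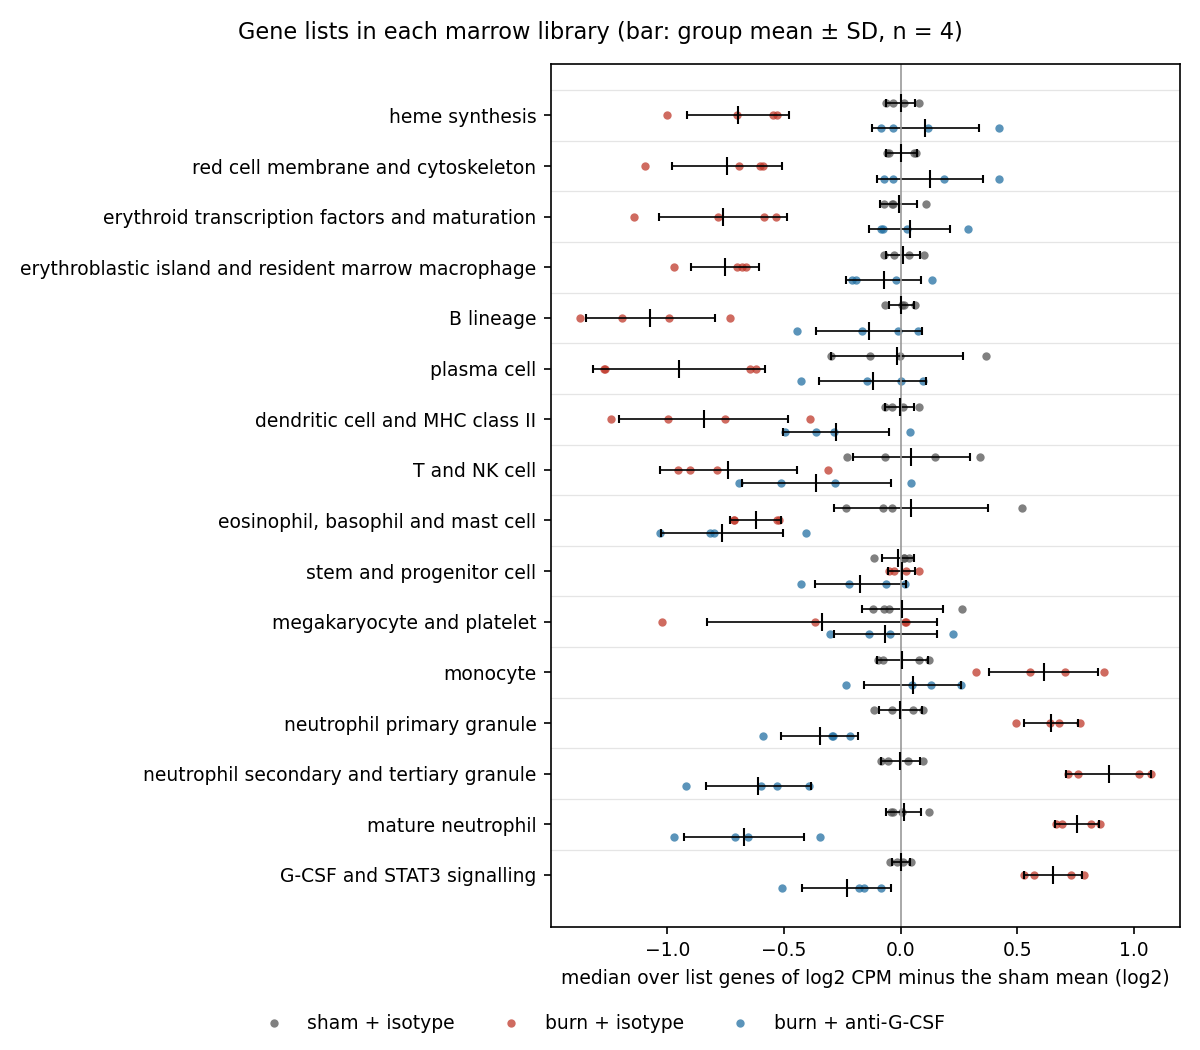
For 16 of the gene lists (vertical axis), the median over list genes of the log2 CPM difference from the sham mean (horizontal axis, log2 units) in each of the 12 libraries, with points for libraries and bars for the group mean ± SD (n = 4). Erythroid, island macrophage and B lineage values lie below 0 in the 4 burn libraries, and values of the 3 neutrophil lists lie above 0 after burn and below 0 with anti-G-CSF. Eosinophil and basophil values lie at -0.40 or below in all libraries of both burn groups. In sham they lie at -0.04, -0.24 and -0.07 in replicates 1 to 3 and at 0.52 in replicate 4.

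Burn with anti-G-CSF was compared with burn with isotype to ask which of these levels depended on G-CSF. Neutrophil genes were lower with the antibody. Most tested genes of the red cell, island macrophage and B lineage lists were higher, though these lists did not pass with an estimated correlation between genes (adjusted p = 0.141 for each of the 3 red cell lists, 0.185 and 0.104). Spic rose from 8.81 ± 2.38 to 15.6 ± 4.32 CPM (SD, n = 4, log2 fold change 0.82 ± 0.20, adjusted p = 0.00463). Csf3r fell from 640.3 ± 45.1 to 234 ± 43.3 CPM (-1.45 ± 0.12, adjusted p = 8.76e-08). In total 2703 genes were higher and 2582 lower, of which 455 and 429 changed over 2-fold. Of the 2703 higher genes 614, and of the 455 over 2-fold higher 150, were among 1293 genes that followed the brain level within groups. With the brain score as a covariate, chosen after seeing the data, 1434 genes were higher and 1619 lower, 2785 of them among the 5285 called without it, and the median SE over genes went from 0.132 to 0.155. Without replicates 9 and 12, also chosen after seeing the data, the counts were 1280 and 1739.

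All 12 tested heme synthesis genes rose with anti-G-CSF (12 adjusted over the list alone), Alas2 by 1.39 ± 0.15, adjusted p = 3.30e-06. The heme synthesis list had a median of 0.81 (camera adjusted p = 1.77e-11, and adjusted p = 0.141 with an estimated correlation). All 17 red cell membrane and cytoskeleton genes rose (17 adjusted over the list alone), the spectrin Sptb by 0.85 ± 0.11, adjusted p = 8.87e-06. The red cell membrane list had a median of 0.88 (camera adjusted p = 1.65e-16, and adjusted p = 0.141 with an estimated correlation). Of 20 erythroid transcription factors and maturation genes 19 rose and 1 fell (19 higher and 1 lower adjusted over the list alone), the latter being Nfe2, which also serves megakaryocytes. The erythroid factor list had a median of 0.81 (camera adjusted p = 8.93e-13, and adjusted p = 0.141 with an estimated correlation). Zfpm1, a cofactor of Gata1, rose by 0.84 ± 0.10, adjusted p = 7.93e-06, Gata1 by 0.65 ± 0.11, adjusted p = 2.39e-04, Klf1 by 0.78 ± 0.12, adjusted p = 1.04e-04 and Epor by 0.81 ± 0.13, adjusted p = 2.55e-04. Of 22 island and resident macrophage genes 16 rose and 1 fell (17 higher and 1 lower adjusted over the list alone), with Vcam1 at 0.69 ± 0.10, adjusted p = 5.40e-05, Mrc1 at 0.87 ± 0.11, adjusted p = 8.10e-06 and Hmox1 at 0.70 ± 0.15, adjusted p = 0.00224, and Maea as the gene that fell. The island macrophage list had a median of 0.70 (camera adjusted p = 1.94e-06, and adjusted p = 0.185 with an estimated correlation). Of 18 iron handling genes 9 rose and 3 fell (9 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.187), with Hp at -1.59 ± 0.13, adjusted p = 9.70e-08.

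Of 13 primary granule genes 12 fell with anti-G-CSF (12 adjusted over the list alone), Ms4a3 at -1.11 ± 0.08, adjusted p = 3.88e-08. The primary granule list had a median of -0.999 (camera adjusted p = 2.60e-17, and adjusted p = 0.0437 with an estimated correlation). All 16 secondary and tertiary granule genes fell (16 adjusted over the list alone), Wfdc21 at -1.77 ± 0.10, adjusted p = 3.43e-09. The secondary granule list had a median of -1.49 (camera adjusted p = 8.95e-42, and adjusted p = 0.0236 with an estimated correlation). Of 18 mature neutrophil genes 17 fell (17 adjusted over the list alone), including Slfn4 (-2.03 ± 0.13, adjusted p = 2.05e-08) and S100a8 (-1.55 ± 0.11, adjusted p = 3.88e-08). The mature neutrophil list had a median of -1.47 (camera adjusted p = 4.92e-38, and adjusted p = 0.0236 with an estimated correlation). Of 14 G-CSF and STAT3 signalling genes 9 fell (9 adjusted over the list alone), with Socs3 going from 36.1 ± 5.01 to 9.67 ± 2.08 CPM (-1.90 ± 0.18, adjusted p = 7.39e-07). The STAT3 signalling list had a median of -0.99 (camera adjusted p = 2.08e-10, and adjusted p = 0.0904 with an estimated correlation). Of 16 monocyte genes 9 fell (10 adjusted over the list alone), Cybb at -1.10 ± 0.12, adjusted p = 1.44e-06. The monocyte list had a median of -0.53 (camera adjusted p = 4.66e-05, and adjusted p = 0.420 with an estimated correlation). Of 10 myeloid suppressor genes 6 fell and 1 rose (2 higher and 6 lower adjusted over the list alone), with the arginase Arg2 at -1.59 ± 0.14, adjusted p = 1.94e-07. The suppressor list had a median of -0.60 (camera adjusted p = 5.37e-04, and adjusted p = 0.0323 with an estimated correlation). Of 19 inflammatory genes 7 fell and 1 rose (1 higher and 7 lower adjusted over the list alone), with the cytokine Osm at -1.60 ± 0.17, adjusted p = 1.94e-06. The inflammatory list had a median of -0.25 (camera adjusted p = 0.0340, and adjusted p = 0.420 with an estimated correlation).

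All 20 B lineage genes rose (20 adjusted over the list alone), Blnk by 0.85 ± 0.11, adjusted p = 2.10e-05. The B lineage list had a median of 0.93 (camera adjusted p = 3.28e-10, and adjusted p = 0.104 with an estimated correlation). Of 8 plasma cell genes 5 rose and 1 fell (5 higher and 1 lower adjusted over the list alone), with Mzb1 at 1.15 ± 0.16, adjusted p = 3.45e-05 and Xbp1 at -0.53 ± 0.10, adjusted p = 6.67e-04. The plasma cell list had a median of 0.89 (camera adjusted p = 0.0256, and adjusted p = 0.420 with an estimated correlation). Of 14 dendritic cell and MHC class II genes 7 rose (7 adjusted over the list alone), Ciita by 0.95 ± 0.14, adjusted p = 5.41e-05. The dendritic cell list had a median of 0.47 (camera adjusted p = 0.0112, and adjusted p = 0.420 with an estimated correlation). Of 28 cell cycle genes 13 rose (13 adjusted over the list alone), Cdc6 by 0.41 ± 0.08, adjusted p = 6.80e-04. The cell cycle list had a median of 0.18 (camera adjusted p = 0.00761, and adjusted p = 0.559 with an estimated correlation). Of 15 eosinophil, basophil and mast cell genes 1 rose and 1 fell (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.824), the riser being the eosinophil chemokine receptor Ccr3 at 0.62 ± 0.14, adjusted p = 0.00388. Of 17 T and NK cell genes 5 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.109), with the cytotoxic granule gene Nkg7 at -0.76 ± 0.13, adjusted p = 1.59e-04.

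Of 14 megakaryocyte and platelet genes 0 rose or fell by edgeR (0 adjusted over the list alone, camera adjusted p = 0.223), 1 had an unadjusted p under 0.05, and 1, Tubb1, passed by the DESeq2 Wald test and limma-voom but 0 by limma-voom with sample weights. Of 17 stem and progenitor genes 4 fell (3 adjusted over the list alone, camera adjusted p = 0.187). Of 24 interferon response genes 6 fell and 2 rose (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.378), with Rsad2 at 1.18 ± 0.15, adjusted p = 2.25e-05. Of 15 stroma and osteoblast genes 3 rose and 1 fell (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.289), of 14 endothelial genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.109) and of 11 skeletal muscle genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.187). Of these 3 lists 2, 1 and 3 members followed the brain level within groups, among them the muscle actin Acta1. When the brain score was added as a covariate 1, 1 and 1 genes of these lists were higher, and the medians went from 0.28, 0.38 and 0.58 to 0.10, 0.075 and 0.066. The Acta1 change of 0.94 ± 0.25, adjusted p = 0.00692 became 0.34 ± 0.22 with the brain score as a covariate (adjusted p = 0.318).

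The largest falls with no overlap between groups were in Lipg (-3.73 ± 0.38, adjusted p = 1.42e-05), Prok2 (-3.65 ± 0.49, adjusted p = 1.22e-04), Upp1 (-3.64 ± 0.19, adjusted p = 1.95e-09), the itaconate-producing enzyme Acod1 (-3.43 ± 0.32, adjusted p = 6.15e-07) and Lrg1 (-2.79 ± 0.20, adjusted p = 4.00e-07). Among the largest rises were those in Alas2, the complement receptor Cr2 of B cells (1.67 ± 0.43, adjusted p = 0.0110), the kinase Mapk11 (1.51 ± 0.23, adjusted p = 6.91e-05) and the red cell enzyme Bpgm (1.40 ± 0.17, adjusted p = 1.24e-05). With library-size scaling alone the split was 5762 higher and 1673 lower, with a median log2 fold change over all genes of 0.26 against 0.08, and with upper quartile scaling it was 3769 and 2193. With only the groups compared it was 1602 and 2475. Without replicate 5 it was 1639 and 2117, and without replicate 11 it was 3045 and 2453. Library-size scaling moved the medians of the inflammatory, interferon and stem and progenitor lists to -0.063, 0.012 and 0.073, and that of the eosinophil and basophil list was positive with it and with upper quartile scaling. With the brain score as a covariate the T and NK cell list, at a median of 0.43 without it, passed at 0.73 (camera adjusted p = 6.66e-05), though not with an estimated correlation as well (adjusted p = 0.304), with 9 genes higher and 1 lower. The interferon list turned from -0.18 to 0.087 (camera adjusted p = 0.244), with 6 genes higher and 1 lower, the eosinophil and basophil list from -0.012 to 0.11 (camera adjusted p = 0.413), and the inflammatory list, at -0.13 (camera adjusted p = 0.215), no longer passed. In the monocyte list 5 genes were then lower and 2 higher, with the median at -0.29 (camera adjusted p = 0.0194, and adjusted p = 0.555 with an estimated correlation as well). Of the B lineage, plasma cell and dendritic cell genes 15, 3 and 10 were higher, and of the primary granule, inflammatory and stem and progenitor genes 10, 4 and 2 lower. With an estimated correlation 4 of the 24 lists passed, those of the 3 neutrophil stages and the myeloid suppressor list. Fry called 18 lists, 11 higher and 7 lower.

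**Figure D3:**
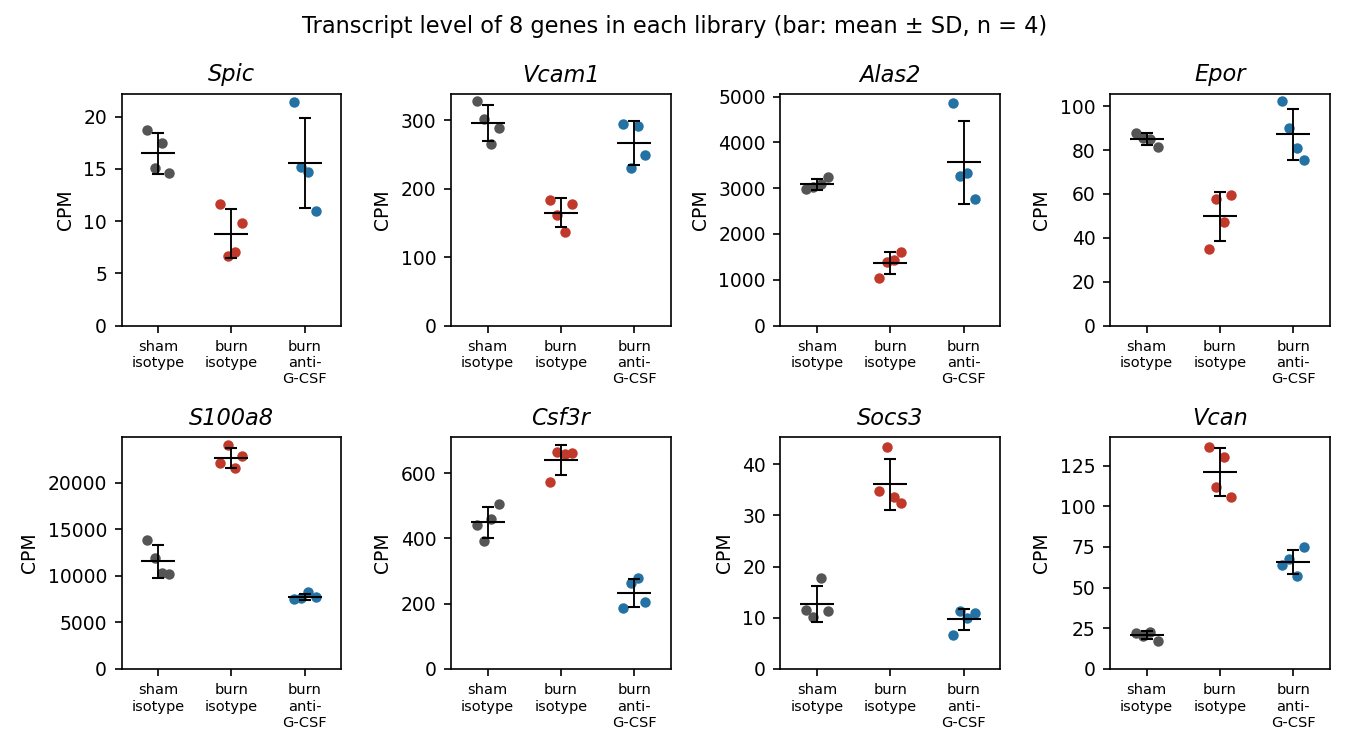
CPM (vertical axes, linear and starting at 0) of Spic, Vcam1, Alas2, Epor, S100a8, Csf3r, Socs3 and Vcan in each library of the 3 groups (horizontal axes), with points for libraries and bars for the group mean ± SD (n = 4). The means of Spic, Vcam1, Alas2 and Epor are lowest in burn with isotype, and the mean of Vcan in burn with anti-G-CSF lies between those of sham and burn.

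Most genes that burn changed were changed the other way by anti-G-CSF. Of the 1691 genes higher after burn 1521 were lower with anti-G-CSF than in burn, and of the 1516 lower after burn 1200 were higher, together 84.8% of the burn calls, while 2 genes changed in the same direction in both comparisons. The balance of the directions moved with the scaling, from 1521 and 1200 to 1099 and 2562 with library-size scaling and 1470 and 1495 with upper quartile scaling. Independent lists of these sizes would share 286 and 268 genes. Both comparisons use the burn libraries, which ties their chance values together. In 20 simulations without effects that shared those libraries the correlation of fold changes across genes was -0.498 and the covariance -0.0322. The observed correlation was -0.538 and the covariance -0.128 across genes, which are not independent replicates. With the 4 burn libraries split into 2 and 2, so that the comparisons shared none, the 6 splits gave 1396 to 2074 genes, correlations of -0.57 to -0.046 and covariances of -0.144 to -0.0165.

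Set against sham, 386 of the 1521 genes raised by burn and lowered by the antibody were lower and 10 higher, with a median log2 fold change of -0.20. Of the 1200 genes lowered by burn and raised by the antibody 0 were lower than sham and 8 higher, with a median of 0.01. The 386 are among 598 genes called lower than sham, a count that was 4 with the brain score as a covariate, 17 without replicates 9 and 12, 177 without replicate 9 and 276 without replicate 12. It was 238, 229 and 253 without replicates 1, 2 and 4, and 376 with library-size scaling. Other settings raised it, to 857 without replicate 11, 739 with DESeq2 size factors, 1007 by the DESeq2 Wald test and 1010 without the 20 most abundant genes.

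Burn with anti-G-CSF was compared with sham to ask what still differed when burn was given with G-CSF neutralised. Neutrophil genes and eosinophil and basophil genes were lower than in sham, though no list passed with an estimated correlation (lowest adjusted p = 0.0826) and no member of these lists passed by edgeR with the brain score as a covariate. No erythroid, island macrophage or B lineage gene of the lists passed the edgeR test. Csf3r stood at 234 ± 43.3 CPM against 449.6 ± 47.3 in sham (SD, n = 4, -0.94 ± 0.12, adjusted p = 4.91e-04), whereas Spic was at 15.6 ± 4.32 against 16.5 ± 1.94 CPM (-0.08 ± 0.20, adjusted p = 0.853). Vcan was higher, at 65.8 ± 7.30 against 20.6 ± 2.50 CPM (1.67 ± 0.11, adjusted p = 2.12e-07). In total 1083 genes were higher and 598 lower, of which 768 and 27 differed over 2-fold.

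Most of the higher genes moved with the brain, heart and lens transcripts. Of the 1083 higher genes 744, and of the 768 over 2-fold higher 603, followed the brain level within groups. Only rising slopes counted as following, and the mean brain level was highest with anti-G-CSF. The 0 such genes among the 598 lower ones therefore do not show that the lower genes are free of this signal. Without all 1293 such genes 335 were higher and 451 lower. With the brain score as a covariate 11 were higher and 4 lower by edgeR, and 881 against 3878 without it passed an unadjusted p of 0.05, while the median SE over genes went from 0.132 to 0.174. Without replicates 9 and 12, which left 2 libraries with anti-G-CSF, 18 were higher and 17 lower. These settings were chosen after seeing the data. The count of 1681 also moved with single libraries, to 349 without replicate 9, 496 without replicate 12, and 386, 443, 1067 and 548 without each of replicates 1 to 4.

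Of 18 mature neutrophil genes 16 were lower (18 adjusted over the list alone), with the chemokine receptor Cxcr2 at -0.94 ± 0.14, adjusted p = 0.00392 and the cytokine Il1b at -2.17 ± 0.29, adjusted p = 0.00412. The mature neutrophil list had a median of -0.62 (camera adjusted p = 1.47e-28, and adjusted p = 0.0826 with an estimated correlation). Of 16 secondary and tertiary granule genes 15 were lower (16 adjusted over the list alone), with Wfdc21 at -0.73 ± 0.10, adjusted p = 9.63e-04. The secondary granule list had a median of -0.60 (camera adjusted p = 7.89e-23, and adjusted p = 0.132 with an estimated correlation). Of 13 primary granule genes 8 were lower and 1 was higher (1 higher and 9 lower adjusted over the list alone), with Cebpe, a transcription factor of granule genes, at -0.64 ± 0.12, adjusted p = 0.00731. The primary granule list had a median of -0.35 (camera adjusted p = 2.20e-05, and adjusted p = 0.369 with an estimated correlation). With the brain score as a covariate the medians of these 3 lists were -0.42, -0.39 and -0.26, no member passed by edgeR although 14, 10 and 5 had an unadjusted p under 0.05, and Csf3r stood at -0.78 ± 0.15, adjusted p = 0.0550. Of 14 G-CSF and STAT3 signalling genes 4 were lower and 1 was higher (1 higher and 5 lower adjusted over the list alone), and the median with the covariate was 0.03. The STAT3 signalling list had a median of -0.22 (camera adjusted p = 2.50e-04, and adjusted p = 0.369 with an estimated correlation). Of 19 inflammatory genes 3 were lower (1 higher and 8 lower adjusted over the list alone). The inflammatory list had a median of -0.20 (camera adjusted p = 5.89e-04, and adjusted p = 0.289 with an estimated correlation).

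Of 15 eosinophil, basophil and mast cell genes 9 were lower (13 adjusted over the list alone), with the basophil proteases Mcpt8 at -0.73 ± 0.12, adjusted p = 0.00453 and Prss34 at -0.69 ± 0.12, adjusted p = 0.00553. The eosinophil and basophil list had a median of -0.72 (camera adjusted p = 2.81e-13, and adjusted p = 0.132 with an estimated correlation). With the covariate the median was -0.54, no member passed by edgeR (7 had an unadjusted p under 0.05), and Mcpt8 stood at -0.54 ± 0.16, adjusted p = 0.493. No gene passed by edgeR in the heme synthesis, red cell membrane, erythroid transcription factor, island macrophage, B lineage, plasma cell, megakaryocyte or cell cycle lists, and 0 did adjusted over the list alone (camera adjusted p = 0.209, 0.0626, 0.679, 0.248, 0.331, 0.324, 0.447 and 0.682 in that order). At an unadjusted p under 0.05 the counts in these lists were 0, 1, 2, 1, 0, 0, 0 and 0. The DESeq2 Wald test passed 2 of their genes, Gfi1b and Tfrc, limma-voom 1, Gfi1b, and limma-voom with sample weights 3, Gfi1b, Tfrc and Slc40a1, all in the erythroid transcription factor and island macrophage lists. The medians of the heme synthesis, red cell membrane and erythroid transcription factor lists were 0.16, 0.17 and 0.05. That of the B lineage list was -0.08, and that of the island macrophage list, -0.05, was positive with upper quartile and library-size scaling. Epor stood at 0.04 ± 0.13, adjusted p = 0.909, Gata1 at -0.08 ± 0.11, adjusted p = 0.719, Klf1 at -0.05 ± 0.12, adjusted p = 0.868, Vcam1 at -0.15 ± 0.10, adjusted p = 0.389 and Hmox1 at -0.01 ± 0.15, adjusted p = 0.974. Gfi1b stood at -0.39 ± 0.13, adjusted p = 0.0558, and at adjusted p = 0.0183 by the DESeq2 Wald test, in a range of 0.00957 to 1.00 over all alternatives.

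Of 16 monocyte genes 1 was higher and 1 was lower (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.736), the former being the nuclear receptor Nr4a1 at 0.77 ± 0.15, adjusted p = 0.0111, which stood at 1.21 ± 0.16, adjusted p = 0.00171 with the covariate. Of 17 T and NK cell genes 2 were lower (2 adjusted over the list alone), with Nkg7 at -0.46 ± 0.13, adjusted p = 0.0287. The T and NK cell list had a median of -0.34 (camera adjusted p = 0.00213, and adjusted p = 0.720 with an estimated correlation). Of 17 stem and progenitor genes 3 were lower (3 adjusted over the list alone). The stem and progenitor list had a median of -0.14 (camera adjusted p = 0.0444, and adjusted p = 0.710 with an estimated correlation). Of 24 interferon response genes 2 were lower (1 adjusted over the list alone). The interferon list had a median of -0.27 (camera adjusted p = 0.00357, and adjusted p = 0.766 with an estimated correlation). Of 14 dendritic cell genes 2 were lower (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0644). Of 18 iron handling genes 1 was lower, Hp at -0.50 ± 0.13, adjusted p = 0.0218 (1 adjusted over the list alone, camera adjusted p = 0.447). Of 10 myeloid suppressor genes 3 were lower (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0626), with Arg2 at -1.16 ± 0.14, adjusted p = 4.58e-04. The list's median was -0.02, its mean 0.04, and the median was positive with upper quartile and library-size scaling.

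Adding the brain score as a covariate changed the calls of 6 of the 24 lists between burn with anti-G-CSF and sham. The monocyte list, at a median of 0.053 without it, passed at 0.35 (camera adjusted p = 4.39e-10), with 1 of its 16 genes past the edgeR threshold, but not with an estimated correlation as well (adjusted p = 0.277). The lists that no longer passed were those of STAT3 signalling, T and NK cell, stem and progenitor, interferon and inflammatory genes, at 0.032 (camera adjusted p = 0.484), 0.12 (camera adjusted p = 0.580), -0.055 (camera adjusted p = 0.262), 0.16 (camera adjusted p = 0.0862) and -0.13 (camera adjusted p = 0.134). Of these the STAT3 signalling, T and NK cell and interferon medians turned positive. Among lists that passed neither way, the dendritic cell median turned from -0.26 to 0.20 (camera adjusted p = 0.179). Those of the iron handling, island macrophage, cell cycle and endothelial lists turned to 0.051 (camera adjusted p = 0.401), 0.021 (camera adjusted p = 0.632), 0.056 (camera adjusted p = 0.104) and -0.019 (camera adjusted p = 0.580), and the iron handling, island macrophage and cell cycle medians were positive with upper quartile and library-size scaling too.

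Of 15 stroma and osteoblast genes 2 were higher (2 adjusted over the list alone, camera adjusted p = 0.447), of 14 endothelial genes 1 was higher (1 adjusted over the list alone, camera adjusted p = 0.209) and of 11 skeletal muscle genes 3 were higher (4 adjusted over the list alone, camera adjusted p = 0.248). The muscle list had a median of -0.07, which was positive with library-size scaling, and a mean of 0.32. Pdgfra at 0.93 ± 0.25, adjusted p = 0.0282, Acta1 at 0.88 ± 0.25, adjusted p = 0.0314 and the muscle creatine kinase Ckm at 1.08 ± 0.29, adjusted p = 0.0322 followed the brain level within groups, and with the covariate they stood at 0.16 ± 0.27, adjusted p = 0.997, 0.09 ± 0.25, adjusted p = 0.997 and 0.01 ± 0.20, adjusted p = 0.997.

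The largest differences above sham with no overlap between groups were in Vcan, Cd300e, a receptor of monocytes (1.57 ± 0.26, adjusted p = 0.00533), Dzank1 (1.53 ± 0.31, adjusted p = 0.0133), Tppp3 (1.52 ± 0.20, adjusted p = 9.47e-04) and the glycine receptor subunit Glrb (1.502 ± 0.33, adjusted p = 0.0169), of which Dzank1 and Glrb followed the brain level within groups. The largest below sham were in Il1b, Foxd4 (-1.33 ± 0.25, adjusted p = 0.00705), Sycp2 (-1.28 ± 0.26, adjusted p = 0.0109), Upp1 (-1.22 ± 0.19, adjusted p = 0.00392) and Lrg1 (-1.16 ± 0.19, adjusted p = 0.00705). With the 20 most abundant genes left out the split was 973 higher and 1010 lower, and with library-size scaling 1294 and 376. Groups did not overlap for 17.0% of tested genes in this comparison, and for 24.7% between burn and sham and 28.9% between the burn groups, where chance gives 2.86%.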

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

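The tests of other splits and of explanations in this part were chosen only after the result was seen. A library stood far from the other 3 of its group, by Dixon's bound for 4 values, in 17 of 294 groups of values, where chance gives 14.7. Among library measures these were the total count of sham replicate 1 (23122127, the others 19684775 to 19924695), the percent of counts in the 20 most abundant genes in replicate 11 (7.49, the others 6.89 to 6.92) and the hemoglobin counts of replicate 12 (55, the others 15 to 21). Among list medians (log2 against the sham mean) they were the island macrophage list in burn replicate 7 (-0.97, the others -0.70 to -0.66), the stem and progenitor list in sham replicate 3 (-0.12, the others 0.02 to 0.04) and the endothelial list in burn replicate 8 (0.24, the others -0.22 to -0.17).

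Among named genes, in CPM, replicate 5 of burn was lowest for Csf3r (573, the others 659.9 to 665), Tubb1 (27.0, the others 51.5 to 53.7) and Sptb (256, the others 339 to 352). Replicate 6 of burn was highest for Car1 (142, the others 105 to 107) and Osm (37.0, the others 20.9 to 23.0). Sham replicate 3 was highest for Prok2 (5.84, the others 1.62 to 2.27) and Ckm (10.99, the others 6.29 to 7.07) and lowest for Nkg7 (35.5, the others 44.2 to 45.4). Sham replicate 1 was lowest for Mapk11 (6.78, the others 11.3 to 11.6), sham replicate 4 was lowest for Il1b (37.7, the others 54.5 to 57.9) and replicate 11 was highest for Lck (32.6, the others 26.1 to 26.6).

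Chance in the grouping of libraries was tested by splitting the 8 libraries of each comparison into 4 and 4 in all 35 ways, fitted on those libraries alone. In each comparison 1 of the 35 splits, the real one, called as many genes as the real one, the smallest share that 35 splits can give. The other splits mix the groups, so a true difference widens their spread. Their counts thus do not show what chance alone would call, and the test does not exclude chance. The real splits called 3395, 4077 and 2003 genes for burn against sham, the burn groups, and burn with anti-G-CSF against sham, and the highest other split called 0 in each. In the last of these the real split also parted the libraries by brain level, at 1260 CPM or more with anti-G-CSF and 874 or less in sham.

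Brain, heart and lens transcripts were present in all libraries, with Camk2a at 106 ± 8.11 CPM in sham and 243 ± 84.2 in burn with anti-G-CSF, and Myh6 at 95.9 ± 7.04 and 227 ± 77.7 (SD, n = 4). The brain level varied 2.94 times among the burn isotype libraries, which were treated alike, from 455 to 1336 CPM. In sham it ran from 664 to 874 CPM. A response to burn could differ between burned libraries, so this spread cannot argue against regulation by burn or antibody. Library size is argued against, since total counts varied 1.37 times and the brain level 5.68 times over the 12 libraries. A candidate source is RNA of 1 outside mixture added in varying amounts, since the ratio of heart to brain transcripts varied 1.12 times over the same libraries. How many of the 18 brain, 14 heart and 12 lens genes marrow itself expresses cannot be read from libraries that all hold them, none is in the marrow lists, and the step at which such RNA could enter stays open.

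Of 49 tested erythroid genes 48 were lower after burn and neutrophil genes were higher, in lists that did not pass with an estimated correlation between genes (adjusted p = 0.0627 or higher), or, for the erythroid lists, with the covariate as well (adjusted p = 0.0948). If neutrophil transcripts had only diluted the rest, stem and progenitor genes would have fallen alike. Their score instead exceeded the erythroid score by 0.75 (log2) more in burn than in sham (exact permutation test, p = 0.0286). That list also holds myeloid genes such as Spi1 and Cebpa, so it cannot settle dilution. The island macrophage, eosinophil, T and NK cell, dendritic cell and B lineage medians fell about as far or further (-0.76, -0.69, -0.72, -0.81 and -1.08). Those of the megakaryocyte, stroma and endothelial lists fell less (-0.28, -0.12 and -0.11). The counts of S100a8, S100a9, Ngp and Ltf alone would shift all other genes by -0.044 (log2). With library-size scaling the median over all genes was -0.10, and the heme synthesis, red cell membrane and erythroid factor medians were -0.77, -0.83 and -0.86. These values argue against an equal dilution of all other transcripts as the whole cause of the erythroid fall. Dilution of lineage genes by a larger share of neutrophil cells stays open. Brain transcripts are argued against by the median of the erythroid genes, -0.73 without and -0.75 with the brain score as a covariate. A change in the share of erythroid cells and a change in transcripts per cell both stay open, untested in whole marrow. The data are consistent with fewer erythroid transcripts after burn as a hypothesis for cell counts to test.

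Of 15 eosinophil, basophil and mast cell genes 12 were lower after burn and 9 after burn with anti-G-CSF than in sham, in a list that did not pass with an estimated correlation (adjusted p = 0.125 and 0.132). A single sham library is argued against, since the list's median stayed at -0.59 (log2) or lower in both comparisons without each sham library. From burn to burn with anti-G-CSF the erythroid score rose 0.98 more than the list's score (exact permutation test, p = 0.0286, the smallest possible). The list's own score changed by -0.14 between the burn groups (exact permutation test, p = 0.429). The list was singled out for being lower in both burn groups. The contrast with erythroid genes on the same libraries therefore describes the pattern and is no separate test of a return with anti-G-CSF. Brain transcripts as the whole cause are argued against by a median of -0.54 or lower in both comparisons with the covariate, which left 9 and 0 genes past the edgeR threshold, the latter as folds shrank and SE grew, with Mcpt8 going from -0.73 ± 0.12 to -0.54 ± 0.16. An effect of burn that does not pass through G-CSF may account for it, and an effect of the antibody itself stays open because sham mice given it were not analysed here.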

How the results depend on the processing

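The settings that use the brain score or leave out replicates 9 and 12 were chosen only after the result was seen. At an adjusted p of 0.01 the counts were 1968 (burn against sham), 3113 (burn groups), 142 (burn with anti-G-CSF against sham) and 1704 (changed oppositely), and in the test against a 1.5-fold change 93, 564, 2 and 71, since both ask for more. With the brain score as a covariate the burn groups gave 3053 genes and burn with anti-G-CSF against sham 15, and without replicates 9 and 12 they gave 3019 and 35. Without the genes that follow the brain score the last comparison gave 786. Leaving out each library in turn gave 2352 to 3254, 3756 to 5530, 349 to 2271 and 1994 to 2713 genes. Every other scaling, filter and test kept these counts within 1.5 times. Camera called 18, 15 and 9 of 24 lists, 0, 4 and 0 with an estimated correlation, 17 to 19, 15 to 16 and 8 to 12 without each library, and 5 in the last comparison with the covariate. With the covariate and an estimated correlation it called 6, 5 and 0. Fry, the other planned list test, called 17, 18 and 7. In the last comparison the covariate turned the medians of 8 lists, those of the interferon list to 0.16 (adjusted p = 0.0862), the T and NK cell list to 0.12 (adjusted p = 0.580) and the STAT3 signalling, dendritic cell, iron handling, island macrophage, cell cycle and endothelial lists to 0.032, 0.20, 0.051, 0.021, 0.056 and -0.019, and turned the muscle gene Ttn to -0.077 (adjusted p = 0.995), and the cause was not tested. Ratios of hemoglobin shares without each library ran from 0.402 to 0.534, 2.20 to 3.45 and 0.981 to 1.54, where 3 against 4 libraries cannot go below an exact p of 0.0571. Of the values of named genes, the covariate ended 44 calls and leaving out replicates 9 and 12 ended 41, against 0 for the DESeq2 Wald test and 8 for library-size scaling. An adjusted p of 0.01 ended 35, the test against a 1.5-fold change 142, and leaving out 1 library 1 to 23. Leaving out hemoglobin genes says nothing, since their counts are so few, and the alternatives on mitochondrial genes were not run because the table holds 0 of them. No paired analysis was possible because no library number is shared between groups. Csf3, with 2 counts in all, was too low to test, and whether depth or a lack of its transcript in marrow is the reason was not tested. The adult hemoglobin genes also had 2 counts in all, while Alas2 took 0.272% and Slc4a1 0.322% of counts on average, which argues against depth as the reason there.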

Other observations

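The test of erythroid stage and the genes in the next sentences were chosen only after the result was seen, while the test of the nonclassical monocyte list was chosen before its result. Between burn with anti-G-CSF and sham, 15 genes passed with the brain score as a covariate, 11 higher and 4 lower, and all 15 were higher in burn with isotype than in sham. The 11 were Smpdl3b, Vcan, Cd300e, Tppp3, Ace, Eno3, S1pr5, Hfe, Nr4a1, Treml4 and Gngt2. Ace, which encodes the angiotensin-converting enzyme, had a log2 fold change (± SE) of 1.40 ± 0.14 without and 1.54 ± 0.19 with it, and Treml4, a receptor of monocytes and macrophages, of 0.66 ± 0.12 without and 1.01 ± 0.13 with it. The 4 lower genes were Card10, Ifitm1, Nlrp12 and Arg2, with the arginase Arg2 at -1.16 ± 0.14 without and -1.21 ± 0.20 with it. Genes higher than sham in both burn groups numbered 60 and genes lower in both 34, while 394 went opposite ways. Independent lists would share 119.8 and 59.3 genes. The covariance of fold changes across genes was 0.0526, against 0.0327 in 20 simulations without effects that shared the sham libraries, but the correlation was 0.253, against 0.504 simulated, across genes that are not independent replicates. With the sham libraries split into 2 and 2 the 6 splits gave 6 to 21 genes, covariances of 0.0136 to 0.0402 and correlations of 0.0525 to 0.172.

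Several of the 11, such as Nr4a1, Ace and Treml4, are known from nonclassical monocytes, which may be more abundant after burn with or without G-CSF as a hypothesis. A separate list of 14 genes of these cells, holding none of the 15, was tested. Its score in burn with anti-G-CSF exceeded sham by 0.079 (log2, exact permutation test, p = 0.629), a negative result by the bound set beforehand. In burn with isotype it exceeded sham by 0.24 (exact permutation test, p = 0.0857). Ceacam1 and Fcgr4 of the list rose after burn (0.89 and 0.78) and fell with anti-G-CSF (-1.08 and -0.996), as neutrophil genes did. Cd36 rose with anti-G-CSF (0.86), as erythroid genes did, while Cx3cr1 and Adgre4 changed little between the burn groups (-0.12 and 0.08). The score may thus reflect other cells of whole marrow, so the negative result does not settle the hypothesis. Of 13 tested genes 2 were higher and 0 lower with anti-G-CSF than in sham. After burn with isotype 5 were higher than in sham and 1, Cd36, lower (-0.75 ± 0.15, adjusted p = 0.00242), and the median gene stood at 0.36, p = 0.0219 by camera (p = 0.229 with an estimated correlation), not a permutation test. The median gene stood at 0.20 with anti-G-CSF against sham, p = 0.0933 by camera (p = 0.371 with an estimated correlation), which is not a permutation test, and at 0.21 with the brain score as a covariate, p = 1.48e-08 by camera (p = 0.00655 with an estimated correlation), so the outcome differs between the planned test and camera with the covariate. No gene of the list passed by edgeR with the covariate in that comparison, the lowest adjusted p being 0.055, for Pou2f2.

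Another hypothesis was that burn lowers late erythroid genes more than early ones, as a block in maturation could. The late minus early score differed by -0.059 (log2) between burn and sham (exact permutation test, p = 0.686), which does not bear it out. Between the burn groups it differed by 0.19 (exact permutation test, p = 0.229) and between burn with anti-G-CSF and sham by 0.13 (exact permutation test, p = 0.314).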
